A study of Drosophila melanogaster with 42 samples.

How the data were processed

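Total RNA of third-instar wing discs was made into paired-end libraries with unique dual indexes from 10 ng of input by 12 to 15 PCR cycles, per the labels, with reads of 150 bases, on a NovaSeq 6000 or a NovaSeq X Plus. The deposited table holds estimated counts per gene, which the authors made with Trimmomatic 0.33, FastQC 0.10 and Salmon 1.80 against the dm6 genome annotation; they also name edgeR for their own tests. The counts are not normalized and were rounded to whole numbers. The table has 17208 genes in 42 columns, and 17083 of the gene identifiers matched the annotation, from which chromosome, position and longest transcript were taken (genome release 6). Each column was matched to its sample by the genotype, sequencer and replicate number in its heading. Polymerase chain reaction copies cannot be told from independent molecules, so intervals and floors cover counting error only.

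Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr for the groups) in R 4.3.3, in 1 fit per sequencer (10775 genes on the X Plus, 10338 on the 6000, residual degrees of freedom 15 each) and in 1 fit of all 42 libraries for comparisons across sequencers (11294 genes). The biological coefficient of variation was 49.2%, 39.4% and 45.5% in the 3 fits. P values were adjusted by Benjamini and Hochberg over a comparison's genes (threshold 0.05). Log2 levels, not fold changes, use a prior count of 2. A change found in each mutant of the 6000 was set against that of Fd5-5 by the difference of both contrasts with their own wild types. Levels are counts scaled to library size with TMM factors (CPM). For a group at 0 counts, the fold is a bound from a floor of 3 counts over the group, and for 1 to 3 counts the ratio has its exact binomial 95% interval.

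The lists of genes, comparisons, tests, named-gene rule and first set of alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 (inter-gene correlation preset at 0.01, in both directions; adjusted over the 360 tests of 36 lists in 10 comparisons with wild type, and for the Yki targets over their own 10), again with the correlation estimated from the data, and with fry. The lists are Yki targets, Hippo components, PCP genes, wing pouch, wing hinge, notum, peripodial, myoblasts, trachea, hemocytes, fat body, salivary gland, muscle, neurons and sensory precursors, testis, cell cycle, apoptosis, JNK and regeneration, JAK/STAT, Wg targets, Notch targets, Dpp targets, Hh targets, EGFR targets, junction and polarity, mitochondrial complexes, glycolysis, ecdysone response, immune effectors, heat shock, ribosomal proteins, cuticle proteins, detoxification, replication histones, mitochondrial genome, and dosage compensation and sex. They were written from general knowledge. Of 17 Yki targets 9 stand also in another list.

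Named genes followed this rule: ft; up to 8 of the largest falls and 8 of the largest rises among genes past the threshold, with a group mean of at least 50 counts and no overlap between groups; the Yki targets past the threshold, and ex, fj, Diap1, CycE, Myc and wg whatever their p; and of each other list called, or with at least 3 members past, up to 4 members of smallest p. The rule gave 1166 pairs of gene and comparison, of which the text prints 181: ft and ex throughout, and from the other parts mostly the 2 of smallest p per list; which lists and extremes to print was settled after the values were seen.

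The alternatives fixed at the start were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a fit of only the 2 groups compared, 1 fit of all 42 libraries with a sequencer term, the replicate number as a block, camera with an estimated correlation, and leaving out each replicate in turn. No pairing of libraries by replicate number was found in residual correlation (mean r −0.02 for same numbers and 0.003 for different ones, 0 of 21 pairs of groups paired), so the block is an alternative. The r of same numbers ran from −0.668 to 0.406, over 0.1 in 19 of 88. In 5 labels the residuals also hold the ribosomal RNA class described below, so this test could miss a pairing. With the replicate block Fd5-5 against wild type had 547 genes, HpoC 481 and HpoN+PH 539. Alternatives added after seeing the data were removal of a trend with transcript length (loess of span 0.3 per library as an offset), the ribosomal RNA class as a term, libraries of 1 class alone, and exclusion of out-of-place libraries. These are nearer another label of their sequencer than their own both on 16 on/off genes and on mean Spearman rho. A first form of the rule used the on/off genes alone and took 11 libraries, with wild type 1 of the 6000, delta A 4 and delta C 1 besides; it was narrowed to 8 after its output was seen, and both are given.

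Similarity to Fd5-5 is Pearson's r across genes, set against data simulated with a shared wild type and no effect. Random lists matched to the Yki targets on transcript length and level were drawn 10000 times. Splits of the same libraries were counted in full up to 35, and otherwise 100 were drawn with a fixed seed. Within groups of 4 to 10 libraries, a value far from the rest was found by Dixon's test. On simulated data with planted 4-fold changes, recovery was 34.9% at the group sizes of Fd5-5, 53.1% at those of HpoC against wild type and 60.6% at those of HpoC against PCP, and with 2-fold changes 1.49% to 19.7%; removal of a planted length trend took false calls from 36 to 7. Of 58 pairs of libraries of the same label 0 were copies of each other. No sample was left out as reported.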

Results

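RNA from wing imaginal discs, which form the adult wing and dorsal thorax, was sequenced from third-instar Drosophila larvae. The 42 libraries carry wild type (w1118.csvd111 in the library names) or mutants of fat (ft), which encodes a giant cadherin that acts upstream of the Hippo pathway and of planar cell polarity. The NovaSeq X Plus gave 21 libraries: wild type (n = 2), Fd5-5 (n = 2), HpoC (n = 5), HpoN+PH (n = 4), PCP (n = 5) and delta D (n = 3). The NovaSeq 6000 gave the other 21: wild type (n = 3), delta A (n = 4), delta B (n = 4), delta C (n = 3), delta E (n = 4) and delta F (n = 3). Functional domains and conserved region D were on the X Plus and the other conserved regions on the 6000, so no mutant was on both. The series names fat nulls without their label; Fd5-5 is left when the named domains and regions are set aside, and is read as the null on that ground alone. Total counts per library ran from 19538208 to 48392354. Each mutant was compared with the wild type of its own sequencer. Levels are counts scaled to library size (CPM), given as mean ± SD, and changes are log2 fold changes with their standard error (SE).

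The gene ft (FBgn0001075, chromosome 2L, 4198404 to 4221796 on genome release 6) was read in every label, Fd5-5 included. Its level was 349 ± 30.4 CPM in wild type and 641 ± 69.7 CPM in Fd5-5 on the X Plus (n = 2 each), and 577 ± 107 CPM in wild type on the 6000 (n = 3). The Yorkie target ex (FBgn0004583, 2L, 431227 to 448701), which encodes a Hippo pathway scaffold and serves as a readout of the pathway, differed between the 2 wild types. It stood at 224 ± 9.37 CPM in wild type on the X Plus (n = 2) and 1563 ± 97.0 CPM in wild type on the 6000 (n = 3). Within HpoC its level was 732 ± 812 CPM (n = 5).

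**Figure D1:**
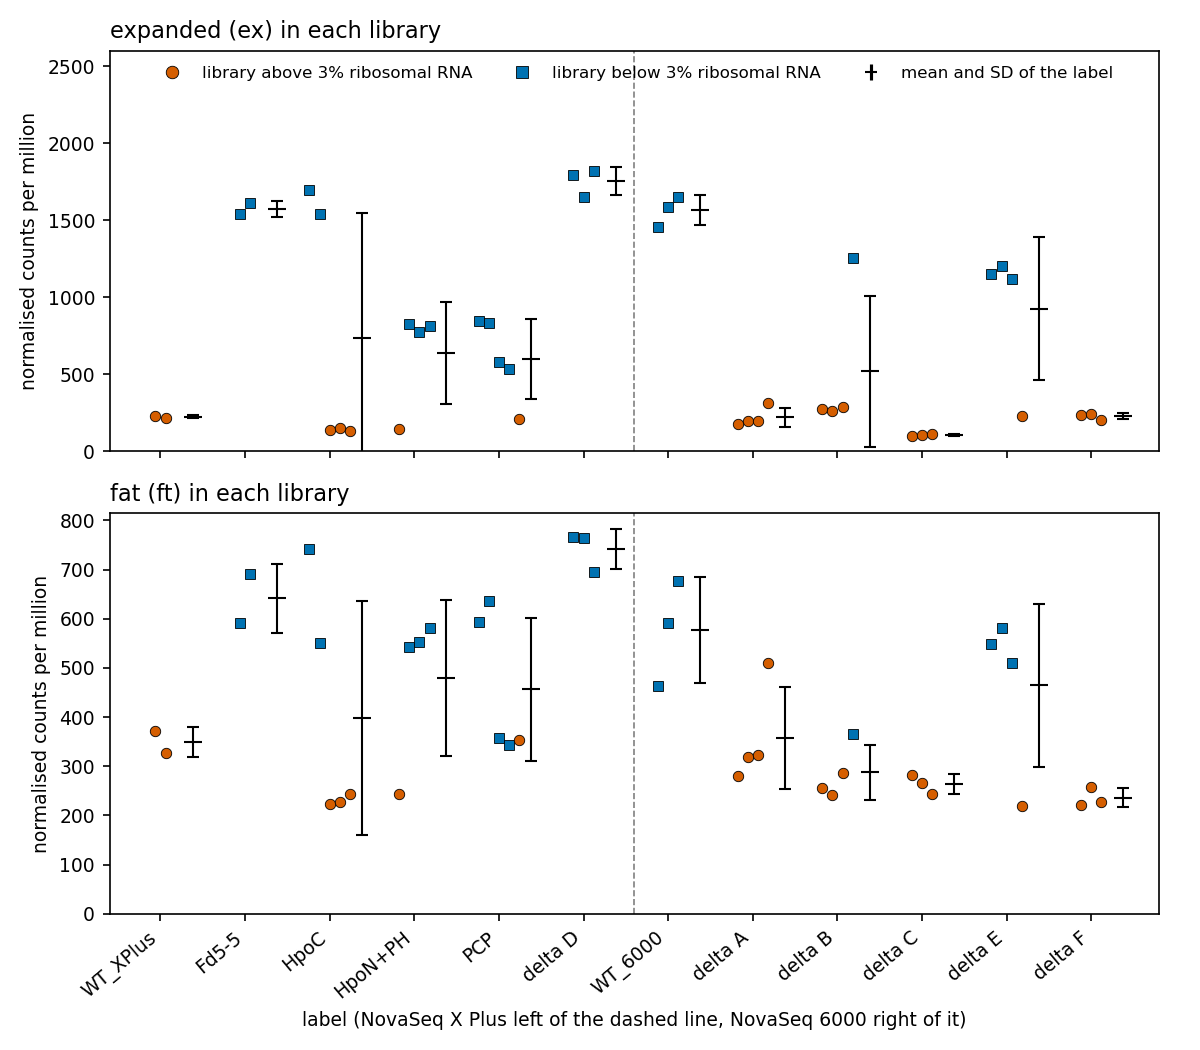
Levels of ex and ft (CPM) in each of the 42 libraries, by label, with mean ± SD; circles are libraries above and squares libraries below 3% of counts on ribosomal RNA genes. The ex level stays at or under 313 in the 21 circles and at or above 533 in the 21 squares, whatever the label.

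Counts on the 46 genes whose symbols contain rRNA set 21 libraries, at 5.11% or more, apart from 21 libraries at 1.68% or less. That division, at 3%, was drawn after the data were seen and is called here the ribosomal RNA class. All libraries of wild type on the X Plus, delta A, delta C and delta F lay above it, and all of wild type on the 6000, Fd5-5 and delta D below it. Delta B, delta E, HpoC, HpoN+PH and PCP held libraries on both sides. The log2 change of level per doubling of transcript length was −0.0798 or lower in every library above 3% and 0.123 or higher in every library below; the longest transcript of ft has 16852 bases and that of ex 6672. Comparisons are given also with the class as a term and, where possible, within 1 class, both set after seeing the data. So was leaving out 8 out-of-place libraries: delta B 4, delta E 4, HpoC 1 and 2, HpoN+PH 1 and PCP 1, 2 and 5. By construction this shrinks spread. The 8 lay nearer another label by mean Spearman rho and 16 genes on in some libraries, off in others (on/off genes). The term rests on 6 of them (not PCP 1 and 2), the smaller class of their labels, so mislabelling would enter it. List calls with the class as a term are by the preset test: 0 of the 82 besides Yorkie targets held with an estimated correlation.

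Many changes below depend on which wild type is the reference. Of the genes changed in each mutant of the X Plus, 422 of 482 (Fd5-5), 356 of 412 (HpoC), 439 of 522 (HpoN+PH), 355 of 389 (PCP) and 2217 of 2858 (delta D) also differed between the 2 wild types in the same way, rising where their wild type was the lower and falling where it was the higher. On the 6000 these numbered 2375 of 6041 (delta A), 1153 of 3332 (delta B), 2190 of 6801 (delta C), 199 of 530 (delta E) and 1956 of 5858 (delta F), and of the named genes that passed 14 of 19, 10 of 15, 10 of 16, 6 of 10 and 8 of 16. In all 10 mutants 0 to 9 genes differed the other way. Such overlap is partly built in, as each mutant shares its wild type with that comparison, and the count was chosen after seeing the data.

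**Figure D2:**
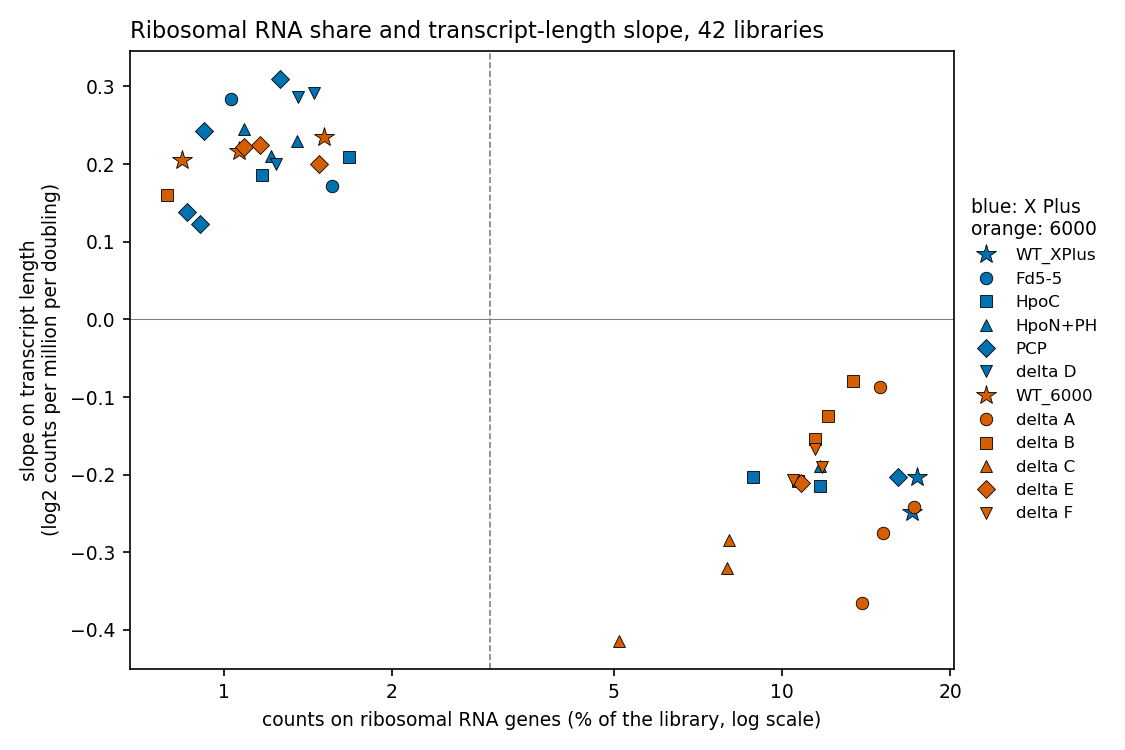
Share of counts on ribosomal RNA genes (percent, log axis) against the log2 change of level per doubling of transcript length, 1 point per library, by label.

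Fd5-5 against wild type asks what loss of Fat does to the wing disc. The JAK/STAT receptor dome (FBgn0043903) rose from 32.5 ± 3.31 to 303 ± 7.5 CPM (log2 3.21, SE 0.55, adjusted p = 0.00225, n = 2 and 2), and its ligand upd1 (FBgn0004956) from 1.13 ± 0.294 to 10.1 ± 2.01 CPM. The posterior genes en (FBgn0000577, log2 2.46) and inv (FBgn0001269, log2 3.07) rose, as did the pouch genes Dll (FBgn0000157, log2 1.68) and rn (FBgn0267337, log2 3.23). Of the Hippo components, yki (FBgn0034970) rose by log2 1.62, the Scalloped corepressor Tgi (FBgn0036373) by log2 3.43 and the ubiquitin ligase subunit Fbxl7 (FBgn0038385) by log2 3.12. Muscle actin Act57B (FBgn0000044) fell from 233 ± 108 to 20.4 ± 11 CPM and muscle troponin C TpnC73F (FBgn0010424) from 135 ± 23.2 to 3.18 ± 0.179 CPM. At the extremes, the salivary glue gene Sgs7 (FBgn0003377) was at 0.0599 ± 0.0847 against 21 ± 15.8 CPM and the p24 family gene p24-2 (FBgn0053105) at 422 ± 46.5 against 1.86 ± 1.28 CPM. All 16 genes named for Fd5-5 that passed differed between the wild types in the same way; in wild type on the 6000 upd1 was at 11.5 ± 1.84, Dll at 156 ± 24.3 and Act57B at 5.43 ± 2.79 CPM (n = 3).

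Among the Yorkie targets, 1 of 16 tested rose in Fd5-5, the cell cycle factor E2f1 (FBgn0011766, log2 1.66, SE 0.32, adjusted p = 0.00563, against 1.83 between the wild types), and 3 rose when adjusted over the list alone (list-adjusted below). Their median was 0.96 (camera adjusted p = 0.00897, adjusted p = 0.454 with an estimated correlation). The level of ex was 1574 ± 51.8 against 224 ± 9.37 CPM (log2 2.80, SE 1.15, adjusted p = 0.140) and ft had a log2 difference of 0.87 (SE 0.54, adjusted p = 0.239); neither passed. In the JAK/STAT list 3 of 9 rose, 4 list-adjusted (camera adjusted p = 0.00113, adjusted p = 0.641 with an estimated correlation). For the wing pouch list 3 of 13 rose, 7 list-adjusted (camera adjusted p = 0.00544, adjusted p = 0.656 with an estimated correlation). Hippo components had 5 of 26 up, 7 up and 1 down list-adjusted (camera adjusted p = 0.0133). Targets of Hedgehog had 3 of 9 up, 5 list-adjusted (camera adjusted p = 0.0140, for both adjusted p = 0.641 with an estimated correlation). The notum list, with toe (FBgn0036285, log2 2.68) and ara (FBgn0015904, log2 1.46), had 6 up and 1 down of 13, 6 and 2 list-adjusted (camera adjusted p = 0.0466, adjusted p = 0.670 with an estimated correlation). Muscle genes had 4 of 13 down, 8 list-adjusted (camera adjusted p = 5.29e-05, adjusted p = 0.641 with an estimated correlation). None of the 88 ribosomal protein genes passed singly, none list-adjusted, at a median of −2.37 (camera adjusted p = 1.40e-12, adjusted p = 0.670 with an estimated correlation). Ribosomal RNA genes took 1.30 ± 0.378% of counts in Fd5-5 and 17.3 ± 0.235% in its wild type (n = 2 each).

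In all, 482 of 10775 genes changed in Fd5-5, 399 up and 83 down (edgeR). The groups did not overlap in 482 of them, but here and below the genes were selected for differing between these libraries. The count was 126 without wild type 1, 69 without wild type 2, 208 without Fd5-5 1 and 284 without Fd5-5 2, and 4, 0, 8 and 10 of the 16 named genes that passed then still did. Wherever 1 of 2 libraries is left, here and below, its spread comes from other labels. The count was 1523 by DESeq2, 5672 in a fit of only the 2 groups and 6723 without the out-of-place libraries, none of which is of Fd5-5 or its wild type. With the ribosomal RNA class as a term 299 of the 482 were called, ex was at 0.12, and the medians were −0.069 for Yorkie targets, not called, −0.01 for Hippo components, 0.45 for the pouch list and 0.04 for ribosomal proteins; of the lists named above the muscle list alone kept its call, at −2.52 (adjusted p = 0.7945 with an estimated correlation).

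HpoC against wild type asks what a mutation of a Fat region tied by its label to Hippo signalling does. The Hippo components yki (log2 2.22, SE 0.35, adjusted p = 0.000813) and Tgi (5.49 ± 1.49 to 86.6 ± 25.2 CPM) rose (n = 5 against 2 here and below). So did dome (32.5 ± 3.31 to 215 ± 78.8 CPM), upd1 (log2 3.11) and the notum genes ara (log2 1.46) and toe (log2 2.64). Muscle myosin light chain Mlc2 (FBgn0002773) fell from 350 ± 182 to 16.1 ± 6.69 CPM and Act57B by 3.56 on the log2 scale. The cuticle genes Lcp1 (FBgn0002531, 94.8 ± 10.6 to 1.56 ± 1.29 CPM) and Cpr60D (FBgn0050163, log2 −2.94) fell. Chaperone gene Hsc70-4 (FBgn0266599) rose from 96.0 ± 18.0 to 8429 ± 2659 CPM and the spindle gene mei-38 (FBgn0260986) from 0.895 ± 0.184 to 77.0 ± 18.6 CPM. In wild type on the 6000 these 2 were at 10690 to 15820 and 62.2 to 79.2 CPM. All 13 genes named for HpoC that passed differed between the wild types in the same way.

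Of the 16 Yorkie targets 1 rose in HpoC, E2f1 (log2 1.36, against 1.83 between the wild types), and 1 list-adjusted, at a median of 0.44 (camera adjusted p = 0.0440, adjusted p = 0.470 with an estimated correlation). That call ended without wild type 2 (median 0.39), HpoC 1 (0.30) or HpoC 2 (0.26). The median was −0.062 with the class as a term, −0.25 within the class of the wild type and −0.23 without the out-of-place libraries, none called. For ex the log2 difference was 1.70 (SE 0.99, adjusted p = 0.464) and for ft 0.18 (SE 0.45, adjusted p = 0.904). Within the class of the wild type, with HpoC 3 to 5 alone, ex was lower at −0.64 and ft at −0.56, both past the threshold. Muscle genes had 8 of 13 down, 11 list-adjusted (camera adjusted p = 4.06e-12) and cuticle proteins had 8 of 59 down, 11 list-adjusted (camera adjusted p = 4.17e-06). The notum list had 6 of 13 up, 7 list-adjusted (camera adjusted p = 0.000426, for all 3 adjusted p = 0.641 with an estimated correlation). JAK/STAT genes had 3 of 9 up, as many list-adjusted (camera adjusted p = 0.00174). Hippo components had 4 of 26 up, 5 list-adjusted (camera adjusted p = 0.00501, for both adjusted p = 0.641 with an estimated correlation). Ribosomal RNA took 6.83 ± 5.04% of counts in HpoC (n = 5).

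In all 412 genes changed in HpoC, 328 up and 84 down, all 412 without overlap between the groups. Without wild type 1 the count was 198 and without wild type 2 it was 105, with 9 and 3 of the 13 named genes that passed still past; it was 4158 without the out-of-place libraries. With the class as a term 411 of the 412 were called and the muscle, cuticle and notum lists kept their calls (medians −3.32, −0.86 and 0.70; adjusted p = 0.7945 with an estimated correlation); JAK/STAT and Hippo lists did not.

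HpoN+PH against wild type tests another Fat region tied by its label to Hippo signalling. The pouch genes Dll (37.2 ± 10.8 to 182 ± 20.1 CPM) and bs (FBgn0004101, log2 2.07) rose, as did the notum genes ara (log2 1.74) and tup (FBgn0003896, log2 1.91; n = 4 against 2 here and below). Posterior genes en (log2 2.67, SE 0.37, adjusted p = 0.000285) and inv (log2 3.09) rose, with dome (log2 3.12) and upd1 (log2 2.88). Tgi rose by log2 4.0 and Cka (FBgn0044323), a phosphatase complex scaffold, by log2 1.07. Heat shock genes Hsp68 (FBgn0001230, 60.2 ± 32.9 to 2.80 ± 0.429 CPM) and DnaJ-1 (FBgn0263106, log2 −0.89) fell, as did Mlc2 (log2 −4.43) and Act57B (log2 −3.03). Of the ecdysone genes, the receptor partner usp (FBgn0003964, log2 1.45) and Eip75B (FBgn0000568, log2 1.83) rose and Eip63F-1 (FBgn0004910) fell by 2.15 on the log2 scale. The chromatin subunit Bap111 (FBgn0030093) rose by log2 5.85, but was at 250 to 320.1 CPM in wild type on the 6000. Of the 19 genes named for HpoN+PH that passed 17, all but DnaJ-1 and Eip63F-1, differed between the wild types in the same way.

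Yorkie targets had 1 of 16 up in HpoN+PH, E2f1 (log2 1.42, against 1.83 between the wild types), 3 list-adjusted, at a median of 0.62 (camera adjusted p = 0.0214, adjusted p = 0.454 with an estimated correlation). The ex difference was log2 1.5 (SE 1.0, adjusted p = 0.331) and that of ft 0.45 (SE 0.47, adjusted p = 0.522). The Yorkie median was −0.16 with the class as a term, not called, and 0.82 without the out-of-place libraries, called. In the class of the wild type only HpoN+PH 1 remains, an out-of-place library; with its spread taken from other labels the Yorkie median was −0.28, ex at −0.62 and ft at −0.48, which says little of the genotype. Muscle genes had 7 of 13 down, 10 list-adjusted (camera adjusted p = 4.03e-07) and the pouch list had 4 of 13 up, 10 list-adjusted (camera adjusted p = 1.52e-05). The notum list had 7 of 13 up, 7 up and 1 down list-adjusted (camera adjusted p = 0.000148, for all 3 adjusted p = 0.641 with an estimated correlation). Heat shock genes had 3 of 14 down, 7 list-adjusted (camera adjusted p = 0.000178) and Hedgehog targets had 5 of 9 up, 5 list-adjusted (camera adjusted p = 0.000558). Hippo components had 5 of 26 up, 6 list-adjusted (camera adjusted p = 0.00113, for all 3 adjusted p = 0.641 with an estimated correlation). JAK/STAT genes had 3 of 9 up, 4 list-adjusted (camera adjusted p = 0.00420). Ecdysone genes had 2 up and 1 down of 23, 10 and 2 list-adjusted (camera adjusted p = 0.0283, for both adjusted p = 0.641 with an estimated correlation). Ribosomal RNA took 3.84 ± 5.23% of counts (n = 4).

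In all 522 genes changed in HpoN+PH, 405 up and 117 down, all without overlap. The count was 173 without wild type 1, 83 without wild type 2 and 1402 without HpoN+PH 1, and 11, 3 and 19 of the 19 named genes that passed then did; 18, 16 and 16 did without HpoN+PH 2, 3 or 4. It was 6804 without the out-of-place libraries. With the class in the model 411 of the 522 were called, and muscle (−2.63), pouch (0.82), notum (0.66), heat shock (−0.77) and Hedgehog (0.75) lists kept their calls (adjusted p = 0.7945 with an estimated correlation); Hippo, JAK/STAT and ecdysone lists did not, nor did bs and Eip75B.

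PCP against wild type asks what a mutation of the Fat region tied by its label to planar cell polarity does. The polarity gene pk (FBgn0003090) rose from 12.9 ± 0.412 to 104 ± 53.9 CPM (log2 3.0, SE 0.66, adjusted p = 0.0131, n = 5 against 2 here and below). Dll (log2 2.0) and kn (FBgn0001319, log2 2.94) rose among pouch genes, and ara (log2 1.75) and B-H2 (FBgn0004854, log2 4.98) among notum genes. The genes upd1 (log2 2.72) and dome (log2 3.15) rose, with en (log2 2.61), inv (log2 3.0), Tgi (log2 3.81) and Cka (log2 0.97). The Mediator subunit kto (FBgn0001324) rose from 3.54 ± 0.402 to 142 ± 77.3 CPM, but was at 5.10 in PCP 5 and at 161 to 296 in wild type on the 6000. The muscle gene Mlp84B (FBgn0014863) fell by 1.93 on the log2 scale. Act57B was at 60.7 ± 42.3 against 233 ± 108 CPM, which did not pass (adjusted p = 0.0720). All 14 genes named for PCP that passed differed between the wild types in the same way.

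Yorkie targets had 1 of 16 up in PCP, E2f1 (log2 1.46, against 1.83 between the wild types), as many list-adjusted, at a median of 0.56 (camera adjusted p = 0.0178, adjusted p = 0.454 with an estimated correlation). The median was −0.17 with the class as a term, not called, and 0.51 without the out-of-place libraries, called. The ex difference was log2 1.41 (SE 0.97, adjusted p = 0.339) and that of ft 0.38 (SE 0.46, adjusted p = 0.57). Genes of planar cell polarity had 1 of 15 up, pk, and 1 list-adjusted, at a median of 0.39 (camera adjusted p = 0.0168, adjusted p = 0.670 with an estimated correlation). The pouch list had 4 of 13 up, 10 list-adjusted (camera adjusted p = 5.29e-05) and the notum list had 7 of 13 up, as many list-adjusted (camera adjusted p = 5.55e-05). JAK/STAT genes had 3 of 9 up, 4 list-adjusted (camera adjusted p = 0.00110, for all 3 adjusted p = 0.641 with an estimated correlation). Hedgehog targets had 4 of 9 up, 5 list-adjusted (camera adjusted p = 0.00126) and Hippo components had 5 of 26 up, 8 list-adjusted (camera adjusted p = 0.00243). No muscle list gene passed, 6 of 13 were down list-adjusted, at a median of −2.25 (camera adjusted p = 5.55e-05, for all 3 adjusted p = 0.641 with an estimated correlation). Ribosomal RNA took 4.01 ± 6.76% of counts (n = 5).

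In all 389 genes changed in PCP, 380 up and 9 down, 335 of them without overlap. The count was 127 without wild type 1, 57 without wild type 2 and 2059 without PCP 5; of the 14 named genes that passed, 6, 2 and 14 then did, and 13 did without PCP 1, 2 or 3. It was 18 in a fit of only the 2 groups, 18 up and 0 down, 1061 by DESeq2 and 5573, 2759 up and 2814 down, without the out-of-place libraries. Given the class as a term 304 of the 389 were called, the pouch (0.70), notum (0.72) and muscle (−1.63) lists kept their calls (adjusted p = 0.7945 with an estimated correlation), and the polarity (−0.07), JAK/STAT, Hedgehog and Hippo lists and pk did not.

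Delta D against wild type asks what a conserved region of the Fat intracellular domain contributes. The JAK/STAT genes dome (329 ± 9.23 against 32.5 ± 3.31 CPM, log2 3.33, SE 0.53, adjusted p = 0.000727) and upd1 (log2 3.55) rose (n = 3 against 2 here and below). The pouch genes Dll (log2 2.13) and dve (FBgn0020307, log2 3.06) and the Hippo components Tgi (log2 3.57) and Fbxl7 (log2 3.21) rose. Muscle genes Act57B (log2 −4.74) and TpnC73F (log2 −6.89), heat shock genes Hsp22 (FBgn0001223, log2 −6.09) and DnaJ-1 (log2 −0.99), and the glycolytic genes Ldh (FBgn0001258, log2 −3.44) and Hex-A (FBgn0001186, log2 −1.05) fell. Ribosomal protein genes RpL10 (FBgn0024733, 1719 ± 50.6 to 272 ± 45.0 CPM) and RpS19b (FBgn0039129, log2 −3.39) fell. The gene mthl8 (FBgn0052475) was read at 0 in delta D, at least 510-fold lower (floor of 3 counts over the group), and ppk13 (FBgn0053508) at 0 in wild type, at least 1960-fold higher in delta D by the same floor. Both are among the 16 on/off genes: in wild type on the 6000 mthl8 was also at 0 and ppk13 at 55.3 to 72.7 CPM, and of the 20 genes named for delta D that passed 19, all but DnaJ-1, differed between the wild types in the same way.

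Of the Yorkie targets, 4 of 16 rose in delta D, as many list-adjusted: E2f1 (log2 1.91, SE 0.31), the Hippo scaffold kibra (FBgn0262127, log2 1.97), the EGFR ligand vn (FBgn0003984, log2 2.74) and CycE (FBgn0010382, log2 0.97), against 1.83, 1.87, 2.44 and 0.86 between the wild types. The list median was 1.14 (camera adjusted p = 0.00223, adjusted p = 0.454 with an estimated correlation). The ex level, 1754 ± 92.3 against 224 ± 9.37 CPM, missed the threshold (log2 2.96, SE 1.11, adjusted p = 0.0554), as did ft (log2 1.08, SE 0.50, adjusted p = 0.10). Ribosomal proteins had 44 of 88 down, 80 down and 1 up list-adjusted (camera adjusted p = 1.03e-11, adjusted p = 0.670 with an estimated correlation). Muscle genes had 9 of 13 down, 11 list-adjusted (camera adjusted p = 6.09e-06) and heat shock genes had 7 of 14 down, 11 list-adjusted (camera adjusted p = 0.000279). Glycolysis genes had 8 of 12 down, 10 list-adjusted (camera adjusted p = 0.00113, for all 3 adjusted p = 0.641 with an estimated correlation). JAK/STAT genes had 5 of 9 up, 6 list-adjusted (camera adjusted p = 0.000426) and the pouch list had 7 of 13 up, 9 list-adjusted (camera adjusted p = 0.000904). Hippo components had 10 up and 2 down of 26, 12 and 4 list-adjusted (camera adjusted p = 0.00400, for all 3 adjusted p = 0.641 with an estimated correlation). Ribosomal RNA took 1.35 ± 0.104% of counts in delta D (n = 3) and 17.3 ± 0.235% in its wild type (n = 2).

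In all 2858 genes changed in delta D, 1210 up and 1648 down, 2856 of them without overlap. The count was 452 without wild type 1, 217 without wild type 2, and 802, 1100 and 869 without delta D 1, 2 and 3; of the 20 named genes that passed, 10, 8, 16, 17 and 16 then did. It was 6884 in a fit of only the 2 groups and 7248 without the out-of-place libraries. Once the class was a term 829 genes were called, the Yorkie median was 0.070, not called, muscle (−3.69), heat shock (−1.65), JAK/STAT (1.0) and pouch (0.73) lists kept their calls (adjusted p = 0.7945 with an estimated correlation), and ribosomal protein, glycolysis and Hippo lists, kibra, CycE, mthl8 and ppk13 did not.

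Between the functional-domain mutants, the comparison of HpoC with PCP asks whether the regions tied to Hippo signalling and to polarity differ in their effect. The gene Hsc70-2 (FBgn0001217) was lower in HpoC, with 1 count against 1927 in PCP (13.3 ± 11.9 CPM, 0.212 to 25.0), a ratio of 1828 (95% counting interval 328 to 72220, without the spread between libraries). CG10505 (FBgn0034612, 0.0918 ± 0.0366 against 2.08 ± 0.563 CPM) and Ddc (FBgn0000422, log2 −2.16, SE 0.36, adjusted p = 0.0309) were lower in HpoC. CG42598 (FBgn0260997) was higher, 25.7 ± 2.69 against 11.5 ± 1.94 CPM (n = 5 each). These 4 of 10775 genes passed, all 4 without overlap, while ex (log2 0.29, SE 0.68, adjusted p = 0.810) and ft (log2 −0.20, SE 0.34, adjusted p = 0.726) did not.

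Leaving out HpoC 1, 2, 3 or 4 left 1 of those 4 genes past; leaving out PCP 1 gave 7 genes and PCP 5 gave 128, and 3 of the 4 passed without HpoC 5 or without PCP 1, 2 or 3. When the class was a term 90 genes passed and within the low class 1166, the 4 named genes in both; in the low class ex was at log2 1.24, past the threshold, with HpoC 1 and 2, both out of place, against 4. Without the out-of-place libraries 6394 genes passed and ex was lower in HpoC at log2 −1.98; there HpoC 3 to 5 lie above 3% ribosomal RNA and PCP 3 and 4 below.

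HpoC and HpoN+PH, the labels tied to Hippo signalling, differed in 0 genes by edgeR, with 1178 at an unadjusted p under 0.05 and 142 called by DESeq2. Without HpoN+PH 1 edgeR called 76. Between them ex differed by log2 0.20 (SE 0.72, adjusted p = 0.886) and ft by −0.27 (SE 0.36, adjusted p = 0.672). Within the low class, with HpoC 1 and 2 alone, 979 genes passed and ex was at log2 1.03. Without the out-of-place libraries 7294 passed and ex was at −2.52, with HpoC 3 to 5 above 3% ribosomal RNA and HpoN+PH 2 to 4 below. HpoN+PH and PCP differed in 0 genes by edgeR, with 489 at an unadjusted p under 0.05 and 68 called by DESeq2; ex differed by log2 0.09 (SE 0.72, adjusted p = 1) and ft by 0.07 (SE 0.36, adjusted p = 1). The class as a term and the low class alone gave 0 there too, but without the out-of-place libraries 3613 genes passed, ex among them at log2 0.54, with HpoN+PH 2 to 4 against PCP 3 and 4.

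Against Fd5-5 the question is how far mutants depart from the null. Delta D differed from it in 66 genes (29 up, 37 down), PCP in 1, HpoC in 2 and HpoN+PH in 0. At an unadjusted p under 0.05 they had 1024, 1222, 1200 and 1673, so no ranking follows. The genes behind the small counts were chosen after their values were seen: IA-2 (FBgn0031294, 0.153 ± 0.150 CPM in HpoC, n = 5, against 18.8 ± 25.1, n = 2) and Myo81F (FBgn0267431, 1 count against 63) for HpoC, and CG3568 (FBgn0029710, log2 −1.97, SE 0.28, adjusted p = 0.0225) for PCP. The delta D count was 22 without Fd5-5 1 and 24, 24 and 29 without delta D 1, 2 and 3. Without Fd5-5 2, with 1 library of Fd5-5 left, HpoC differed in 68 genes, HpoN+PH in 14 and PCP in 40, and HpoN+PH in 13 without HpoN+PH 1. The HpoC count fell to 0 without Fd5-5 1 or HpoC 2, 3, 4 or 5 and to 1 without HpoC 1, and the PCP count to 0 without Fd5-5 1 or PCP 1, 2, 3 or 4. Under the class term the counts were 461 for delta D, 242 for PCP, 255 for HpoN+PH and 0 for HpoC.

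Across genes, the changes of each X Plus mutant went with those of Fd5-5: Pearson's r was 0.77 for HpoC, 0.72 for HpoN+PH, 0.80 for PCP and 0.82 for delta D. Genes are not independent replicates, and all share 1 wild type; data simulated with no effect but that shared control gave 0.60, 0.58, 0.60 and 0.55. Genes called up in both numbered 285 for HpoC, 315 for HpoN+PH, 311 for PCP and 375 for delta D; the number the shared wild type alone would give was not computed. After adding the class term r was 0.83, 0.57, 0.57 and 0.62, and without the out-of-place libraries HpoC came to 0.31.

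Delta A and the following 4 mutants ask the same of the conserved regions run on the 6000. The Yorkie target ex fell from 1563 ± 97.0 to 220 ± 62.8 CPM (log2 −2.86, SE 0.54, adjusted p = 0.00120), with kibra (log2 −1.73), CycE (log2 −0.91) and the glypican gene dally (FBgn0263930, log2 −1.55; n = 4 against 3 here and below). Fat body genes rose, Fbp2 (FBgn0000640) from 1.17 ± 0.458 to 548 ± 513 and Obp99b (FBgn0039685) from 1.32 ± 0.270 to 717 ± 766 CPM, as did muscle genes TpnC73F (log2 6.33) and Act57B (log2 4.42). The protease gene Jon65Aiv (FBgn0250815) rose from 0.205 ± 0.0600 to 701 ± 877 CPM. Carry-over of other tissue was not tested for any label. The Dpp targets magu (FBgn0262169, log2 −1.58) and brk (FBgn0024250, log2 −1.97), both of which Dpp signalling represses, and the polarity complex genes Patj (FBgn0067864, log2 −0.82) and sdt (FBgn0261873, log2 −2.52) fell. Notch targets E(spl)mdelta-HLH (FBgn0002734, log2 1.74) and E(spl)malpha-BFM (FBgn0002732, log2 2.12) rose. RpS19b (log2 3.63) and RpL22-like (FBgn0034837, log2 2.40) rose, and 28SrRNA:CR45837 (FBgn0267497), at 135013 ± 17110 CPM, was at 0 in wild type, at least 3933612-fold lower by the group floor.

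Yorkie targets had 12 of 16 down in delta A, 13 list-adjusted, at a median of −1.24 (camera adjusted p = 0.000453, adjusted p = 0.454 with an estimated correlation). The gene ft fell by 0.72 on the log2 scale (SE 0.28, adjusted p = 0.0356). Fat body genes had 11 of 11 up, all list-adjusted too (camera adjusted p = 1.31e-05) and muscle genes had 12 of 13 up, as many list-adjusted (camera adjusted p = 9.40e-05). Notch targets had 11 up and 1 down of 14, alike list-adjusted (camera adjusted p = 0.000618, for all 3 adjusted p = 0.641 with an estimated correlation). Dpp targets had 6 of 8 down, 7 list-adjusted (camera adjusted p = 0.00149). Junction and polarity genes had 19 down and 1 up of 22, alike list-adjusted (camera adjusted p = 6.50e-05, for both adjusted p = 0.641 with an estimated correlation). Ribosomal proteins had 82 of 88 up, 83 list-adjusted (camera adjusted p = 3.84e-13, adjusted p = 0.656 with an estimated correlation). Ribosomal RNA took 15.3 ± 1.38% of counts in delta A (n = 4) and 1.14 ± 0.343% in its wild type (n = 3).

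In all 6041 of 10338 genes changed in delta A, 3139 up and 2902 down, 5539 of them without overlap. Of the 19 named genes 18 passed without wild type 2 or 3 or without delta A 1, 2 or 3. With the class as a term 436 genes were called, ex was at −0.56 and the Yorkie list at −0.24, neither called, ft was at 0.22, and dally at 0.08. The fat body (9.53), muscle (3.28), Notch (0.44) and Dpp (−0.41) lists kept their calls (adjusted p = 0.7945 with an estimated correlation), as did magu and brk; the ribosomal protein list was called the other way (−0.15; adjusted p = 0.9078 with an estimated correlation) and the junction list not. With the length trend removed ft was at 0.48.

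In delta B heat shock genes rose against wild type, Hsp26 (FBgn0001225) from 36.2 ± 4.72 to 2036 ± 1354 CPM (log2 5.79, SE 0.87, adjusted p = 0.00265), Hsp22 from 0.317 ± 0.171 to 251 ± 177 CPM and Hsp70Ab (FBgn0013276) by log2 10.16 (n = 4 against 3 here and below). The death genes egr (FBgn0033483, log2 1.32) and rpr (FBgn0011706, log2 1.85) rose, as did E(spl)m2-BFM (FBgn0002592, log2 1.28). The polarity genes baz (FBgn0000163, log2 −1.24) and par-6 (FBgn0026192, log2 −0.53) fell. Ribosomal protein genes RpL22-like (log2 2.05) and RpS15Ab (FBgn0033555, log2 1.08) rose, with mt:ND3 (FBgn0013681, log2 3.86) of the mitochondrial genome. The gene 28SrRNA:CR45837 was at 84020 ± 57340 CPM against 0 in wild type.

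The level of ex fell by 1.62 on the log2 scale (SE 0.53, adjusted p = 0.0316), ft by 1.03 (SE 0.28, adjusted p = 0.0193) and CycE by 0.63. Yorkie targets had 3 of 16 down, 1 list-adjusted, at a median of −0.50 (camera adjusted p = 0.0101, adjusted p = 0.454 with an estimated correlation). Heat shock genes had 14 of 14 up, all list-adjusted too (camera adjusted p = 5.17e-07). Apoptosis genes had 5 of 11 up, as many list-adjusted (camera adjusted p = 0.0299, for both adjusted p = 0.641 with an estimated correlation). Notch targets had 8 of 14 up, as many list-adjusted (camera adjusted p = 0.0282, adjusted p = 0.656 with an estimated correlation). Junction and polarity genes had 11 of 22 down, 15 list-adjusted (camera adjusted p = 0.000178, adjusted p = 0.646 with an estimated correlation). Ribosomal proteins had 85 of 88 up, 87 list-adjusted (camera adjusted p = 2.99e-17, adjusted p = 0.641 with an estimated correlation). Genes of the mitochondrial genome had 5 of 15 up, 6 list-adjusted (camera adjusted p = 0.0349, adjusted p = 0.723 with an estimated correlation). Ribosomal RNA took 9.44 ± 5.83% of counts (n = 4).

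In all 3332 genes changed in delta B, 2009 up and 1323 down, 2005 of them without overlap. The count was 1860, 109 and 216 without wild type 1, 2 and 3, and 1137, 632, 566 and 5837 without delta B 1, 2, 3 and 4; of the 15 named genes that passed, 12, 2, 2, 10, 9, 9 and 15 then did. It was 0 in a fit of only the 2 groups and 6637 without the out-of-place libraries. With the class in the model 11 genes were called and none of the 15 named genes, and within the class of the wild type, with delta B 4 alone, an out-of-place library with its spread taken from other labels, 0 by edgeR; the Yorkie median was 0.081 with the term, not called, the heat shock (2.62) and apoptosis (0.31) lists kept their calls with the term, the mitochondrial genome was called the other way (−1.24; adjusted p = 0.7945 with an estimated correlation for all 3), Notch, junction and ribosomal protein lists were not called, and mt:ND3 was at −0.53. With the length trend removed ft was at 0.39.

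In delta C, which had the largest of the 10 counts against wild type, ex fell from 1563 ± 97.0 to 103 ± 5.49 CPM (log2 −3.95, SE 0.63, adjusted p = 0.000189, n = 3 each here and below), with crb (FBgn0259685, log2 −2.96), the Notch ligand Ser (FBgn0004197, log2 −2.61) and kibra (log2 −2.31). Septate junction genes cora (FBgn0010434, 829 ± 48.1 to 168 ± 21 CPM) and Nrx-IV (FBgn0013997, 918 ± 80.1 to 180 ± 35.6 CPM) fell. The planar polarity genes frtz (FBgn0086698, log2 −1.17) and dgo (FBgn0086898, log2 −0.81), and magu (log2 −1.70) and brk (log2 −1.99), fell, and E(spl)malpha-BFM (log2 2.43) and E(spl)mdelta-HLH (log2 1.84) rose. RpLP0-like (FBgn0033485) rose by log2 1.48. CG46312 (FBgn0284228) was at 0 in delta C and 61.2 ± 19.1 CPM in wild type, at least 2007-fold lower. Like ppk13 it is an on/off gene, at 0 in both wild type libraries of the X Plus. The gene 28SrRNA:CR45837 was at 47400 ± 16870 CPM against 0 in wild type.

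Yorkie targets had 12 of 16 down in delta C, as many list-adjusted, at a median of −1.31 (camera adjusted p = 0.000726, adjusted p = 0.454 with an estimated correlation). The gene ft fell by 1.16 on the log2 scale (SE 0.31, adjusted p = 0.00335). Junction and polarity genes had 20 down and 1 up of 22, alike list-adjusted (camera adjusted p = 1.31e-05) and Notch targets had 12 of 14 up, as many list-adjusted (camera adjusted p = 0.000507). Dpp targets had 7 of 8 down, 8 list-adjusted (camera adjusted p = 0.00240, for all 3 adjusted p = 0.641 with an estimated correlation). Genes of planar cell polarity had 11 down and 1 up of 15, 12 and 1 list-adjusted (camera adjusted p = 0.00418, adjusted p = 0.641 with an estimated correlation). Ribosomal proteins had 87 of 88 up, as many list-adjusted (camera adjusted p = 4.17e-14, adjusted p = 0.656 with an estimated correlation). Ribosomal RNA took 7.05 ± 1.68% of counts in delta C (n = 3).

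In all 6801 genes changed in delta C, 3497 up and 3304 down, 6675 of them without overlap. Of the 16 named genes that passed 15 did without delta C 1, 2 or 3. Given the class as a term 1346 genes were called, ex at −1.64, kibra, cora, Nrx-IV, magu, brk and frtz among them, the junction (−0.53), Notch (0.87), Dpp (−0.69) and ribosomal protein (0.33) lists kept their calls (adjusted p = 0.7945 with an estimated correlation), as did the Yorkie list (−0.62; adjusted p = 0.970 with an estimated correlation), and the polarity list (−0.42) did not; 28SrRNA:CR45837 was then at −0.99 and CG46312 at −0.15. With the length trend removed ft was at 1.09, past the threshold in the other direction.

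In delta E the ecdysone-induced gene ImpE2 (FBgn0001254) rose from 471 ± 83.0 to 5043 ± 1476 CPM (log2 3.41, SE 0.54, adjusted p = 0.00213, n = 4 against 3 here and below) and ImpE3 (FBgn0001255) by log2 2.70. The sensory precursor genes sens (FBgn0002573, 4.55 ± 0.390 to 13.9 ± 3.81 CPM) and ase (FBgn0000137, log2 3.5) and the Notch targets E(spl)malpha-BFM (log2 1.36) and E(spl)m4-BFM (FBgn0002629, log2 1.5) rose. Act57B (log2 2.52) and TpnC73F (log2 3.27) rose. Of the channel genes, Ih (FBgn0263397) rose from 0.160 ± 0.0193 to 54.2 ± 35.8 CPM and SK (FBgn0029761) fell from 64.7 ± 17.7 to 2.38 ± 0.208 CPM.

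The level of ex was 924 ± 464 against 1563 ± 97.0 CPM (log2 −0.76, SE 0.52, adjusted p = 0.427) and the ft difference log2 −0.32 (SE 0.28, adjusted p = 0.560); neither passed. Yorkie targets had 0 of 16 past in delta E by edgeR, 0 list-adjusted, at a median of −0.17 (camera adjusted p = 0.0754, adjusted p = 0.470 with an estimated correlation). By the preset test alone that list was called without wild type 2 (median −0.18), delta E 1 (−0.25), delta E 2 (−0.27) or delta E 3 (−0.22). Its median was 0.07 without delta E 4 and 0.048 with the class as a term. Notch targets had 5 of 14 up, 9 list-adjusted (camera adjusted p = 1.50e-06) and neuron and sensory precursor genes had 4 of 12 up, 7 list-adjusted (camera adjusted p = 5.38e-05). Muscle genes had 3 of 13 up, 4 list-adjusted (camera adjusted p = 0.00110, for all 3 adjusted p = 0.641 with an estimated correlation). Ecdysone genes had 7 up and 1 down of 24, 9 and 4 list-adjusted, and the list was not called (camera adjusted p = 0.0594, adjusted p = 0.641 with an estimated correlation). Ribosomal RNA took 3.64 ± 4.79% of counts (n = 4).

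In all 530 genes changed in delta E, 298 up and 232 down, 470 of them without overlap. The count was 145 without wild type 2, 291 without wild type 3, 257 without delta E 1 and 307 without delta E 2; it was 146 in a fit of only the 2 groups and 1630 without the out-of-place libraries. Of the 10 named genes that passed, 7, 7 and 8 did without wild type 1, 2 and 3 and 9 without delta E 4. Once the class was a term 968 genes were called and within the class of the wild type, delta E 1 to 3 against 3, 1487; all 10 named genes passed in both, the Notch (0.65), neuron (0.86) and muscle (2.02) lists kept their calls with the term (adjusted p = 0.7945 with an estimated correlation), and within the class ex was lower at log2 −0.45, past the threshold.

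In delta F ex fell from 1563 ± 97.0 to 227 ± 21.1 CPM (log2 −2.85, SE 0.60, adjusted p = 0.00284, n = 3 each here and below), with kibra (log2 −1.82) and dally (log2 −1.60). The junction genes l(2)gl (FBgn0002121, 708 ± 94.4 to 144 ± 10.6 CPM) and pyd (FBgn0262614, log2 −2.08) fell. Blood cell genes Hml (FBgn0029167, 22.9 ± 11.1 to 0.925 ± 0.165 CPM), NimC1 (FBgn0259896, log2 −3.47) and Sr-CI (FBgn0014033, log2 −2.66) fell. The Dpp targets magu (log2 −1.57) and brk (log2 −1.46) and the planar polarity gene frtz (log2 −0.73) fell, and E(spl)malpha-BFM (log2 1.71) and RpL22-like (log2 2.29) rose. CG46312, at 0 in delta F, was at least 1837-fold lower, and 28SrRNA:CR45837 was at 97450 ± 7366 CPM against 0 in wild type.

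Yorkie targets had 10 of 16 down in delta F, as many list-adjusted, at a median of −0.99 (camera adjusted p = 0.00223, adjusted p = 0.454 with an estimated correlation). The gene ft fell by 1.36 on the log2 scale (SE 0.31, adjusted p = 0.00316). Junction and polarity genes had 18 of 22 down, 19 down and 1 up list-adjusted (camera adjusted p = 6.60e-05, adjusted p = 0.641 with an estimated correlation). Hemocyte genes had 7 of 12 down, as many list-adjusted (camera adjusted p = 0.0304, adjusted p = 0.656 with an estimated correlation). Notch targets had 11 of 14 up, as many list-adjusted (camera adjusted p = 0.00119) and Dpp targets had 7 of 8 down, 8 list-adjusted (camera adjusted p = 0.00470). Genes of planar cell polarity had 11 down and 1 up of 15, 12 and 1 list-adjusted (camera adjusted p = 0.00501, for all 3 adjusted p = 0.641 with an estimated correlation). Ribosomal proteins had 87 of 88 up, as many list-adjusted (camera adjusted p = 2.99e-17, adjusted p = 0.641 with an estimated correlation). Ribosomal RNA took 11.3 ± 0.694% of counts in delta F (n = 3).

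In all 5858 genes changed in delta F, 2912 up and 2946 down, 5749 of them without overlap. Of the 16 named genes 15 passed without wild type 3 or delta F 1, 2 or 3. When the class was a term 29 genes were called, 1 of the 16 named genes, magu; ex was then at −0.54, the Yorkie list at −0.14 and dally at 0.03, and the junction (−0.17), Notch (0.38) and ribosomal protein (0.096) lists kept their calls (adjusted p = 0.7945 to 0.9078 with an estimated correlation), while the hemocyte, Dpp and polarity lists did not. With the length trend removed ft was at 0.66, past the threshold in the other direction.

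Taken across sequencers, the effect on Yorkie targets was lower in each conserved-region mutant of the 6000 than in Fd5-5, each effect measured against its own wild type. The difference passed for 11 of 16 targets in delta A, 8 in delta B, 10 in delta C, 6 in delta E and 10 in delta F, all of them lower, with median differences of −2.24, −1.60, −2.48, −1.08 and −2.07. Without wild type 2 of the X Plus the numbers for delta B and delta E were 5 and 3. Across genes the changes correlated with those of Fd5-5 at r = −0.60 for delta A, −0.53 for delta B, −0.64 for delta C, −0.36 for delta E and −0.63 for delta F; genes are not independent replicates. Of the genes up in Fd5-5, 315, 18, 166, 11 and 94 were down in these mutants, where independent lists give 112, 51.1, 127, 8.96 and 114, and 3 to 6 were up. Under the class term 0 targets differed in each of the 5 by edgeR, and r was −0.42, −0.15, −0.07, −0.17 and −0.07.

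**Figure D3:**
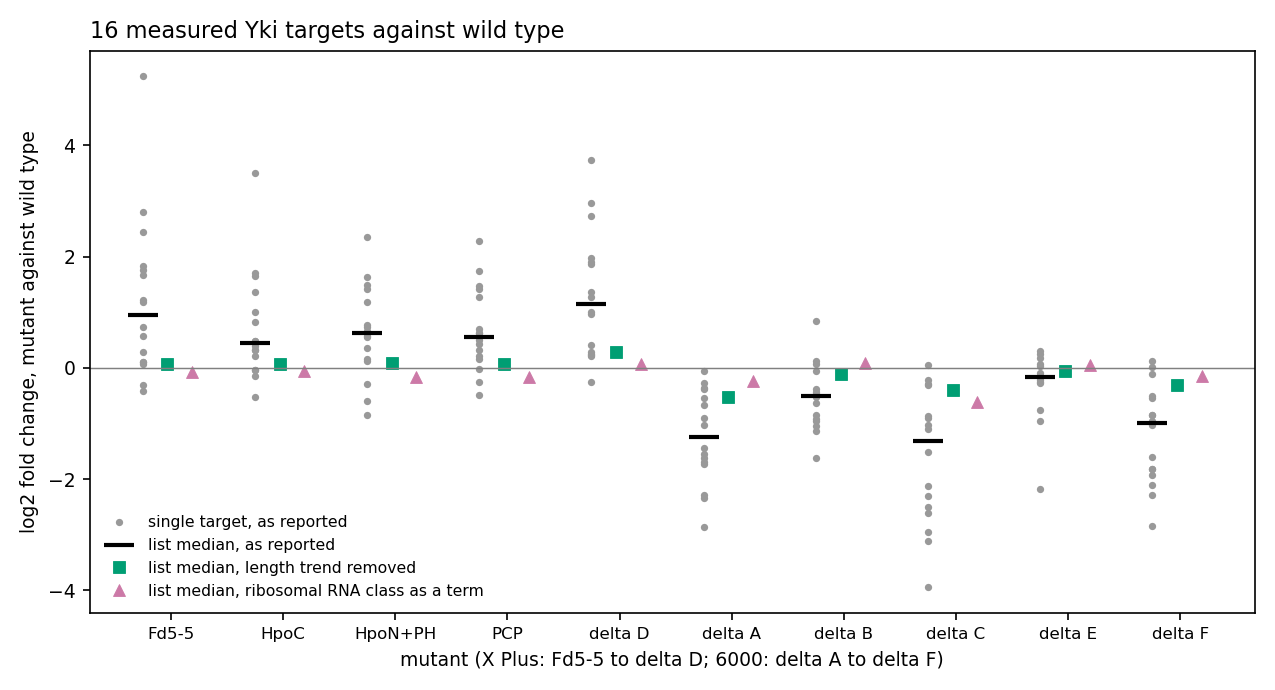
Median log2 change of the 16 tested Yorkie targets in each mutant against the wild type of its sequencer, as reported, with the transcript-length trend removed and with the ribosomal RNA class as a term. The reported medians run from −1.31 in delta C to 1.14 in delta D.

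Wild type on the X Plus and on the 6000 share a strain name. The level of ex was 224 ± 9.37 against 1563 ± 97.0 CPM and ft 349 ± 30.4 against 577 ± 107 CPM (n = 2 and 3). Ribosomal proteins had 60 of 88 higher on the X Plus, 79 list-adjusted (camera adjusted p = 2.59e-13, adjusted p = 0.429 with an estimated correlation). Salivary gland genes had 4 of 9 higher, 5 list-adjusted (camera adjusted p = 0.00147). Wing hinge genes had 5 of 10 lower, 6 lower and 1 higher list-adjusted (camera adjusted p = 0.00368, for both adjusted p = 0.404 with an estimated correlation). In all 2790 of 11294 genes differed, 1547 higher and 1243 lower on the X Plus; the count was 444 and 43 with 1 library of the X Plus left, without wild type 1 or 2, and 1444, 1393 and 1627 without 1, 2 or 3 of the 6000. Sequencer, ribosomal RNA class and label coincide here, and they cannot be told apart from this comparison; with the class as a term, drawn from the mutants that hold both sides, 752 genes differed.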

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

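The tests of mislabelled libraries, of the sequencer, of the wild type group, of the ribosomal RNA class, of the labelled genotypes and of the length trend in the classes were chosen only after the results were seen; the bounds of the splits and of the length trend in the other 2 patterns were set before their own results, but after the data had been looked at.

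Libraries of 1 label fell into different classes: 5 labels held libraries on both sides of 3% ribosomal RNA, and for 12 libraries the nearest library of the same sequencer carried another label. A trend with transcript length alone is argued against, since 12 were still nearest to another label after it was removed. Mislabelled libraries may account for the pattern: 8 were nearer another label on on/off genes and on expression, and pairs of 1 label in different classes differed in a median of 6 of the 16 on/off genes against 1 in the same class. A ribosomal RNA class set by the preparation cannot be told apart from this, because 6 of the 8 lie in the smaller class of their label, and within a class 3 libraries (wild type 1 of the 6000, PCP 1 and PCP 2) were still nearer another label by at least 2 on/off genes. No biological explanation was tested.

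Across genes, the changes of the 6000 mutants correlated negatively with those of Fd5-5 on the X Plus. A sequencer difference is argued against: the median Spearman rho of wild type on the 6000 with delta D on the X Plus was 0.9887, as between delta D libraries, and 0.914 with the X Plus wild type; so is the transcript-length trend as the whole cause, since with it removed all 5 mutants of the 6000 still correlated with Fd5-5 at −0.323 or lower. A wild type group that holds other flies than its label says may account for it, with a median of 11.5 on/off genes between the 2 wild types, against 3 between wild type on the 6000 and delta D. The ribosomal RNA class cannot be told apart from it, since with the class as a term 3 of the 5 mutants of the 6000 still correlated below −0.1 with Fd5-5 and both wild types lie in 1 class each. Effects of the labelled mutations stay open and were not tested.

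Yorkie targets stood apart from other genes in 9 of 10 comparisons with wild type by the preset test. The transcript-length trend may account for it: the list median left the range of 10000 random lists matched on length and level in 0 of 10 comparisons (percentiles 7.39 to 86.95, adjusted p 0.850 to 0.986). The ribosomal RNA class cannot be told apart from the genotype: with it as a term 1 of 10 comparisons, delta C, kept its call, while for 5 of the 10 mutants every library differs in class from every wild type library. The labelled fat genotypes stay open, since 4 of the 5 mutants of the 6000 had a negative median without the 8 out-of-place libraries.

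Other splits of the same libraries show how far chance can be excluded. For delta A, where label and class split alike, it can only as far as 35 splits allow. The label split gave 6041 genes, 1 of 35 as many, and the highest other 4594. For delta B it cannot, with 3332 genes, 2 of 35 and 6071 when delta B 4 was placed with the wild type, nor for delta E, with 530, 3 of 35 and 580. For delta C and delta F there are too few splits, 10 each, with 6801 and 5858 genes and 0 as the highest other. For HpoC against PCP, 6 of 100 splits gave at least its 4 genes, up to 5874 with HpoC 1 and 2 and PCP 1, 2 and 4 set against the rest, where the low class alone gives 1166. HpoC against HpoN+PH and HpoN+PH against PCP had 0 genes, so splits decide nothing. Single ones gave up to 7105, where the split follows the class, and 222.

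Of 36 tests for a library far from the others of its label 10 were met, where chance gives 1 in 20 groups, or 1.8. Delta A 4 had 12130 genes detected (others 11456 to 11541) and ex at 313 CPM (176 to 197). Delta B 4 had ex at 1256 CPM (259 to 284). Delta E 4 had a length slope of −0.211 (0.201 to 0.225), ex at 230.1 CPM (1115 to 1204) and a mean log2 level of Yorkie targets of 6.56 (7.39 to 7.54). HpoN+PH 1 had a length slope of −0.189 (0.210 to 0.245), ft at 243 CPM (543 to 580.2), ex at 142 CPM (774 to 823) and a Yorkie mean of 6.22 (7.28 to 7.32). Among the genes named by the rule, delta A 4 stood far from its label in 15 (others 0 to 4), delta B 4 in 47 (0), delta E 4 in 24 (0 to 2), HpoC 3 in 2 (0 to 1), HpoN+PH 1 in 23 (1 to 6) and PCP 5 in 45 (0 to 3). Yorkie targets whose effect differed from that in Fd5-5 numbered 11, 8, 10, 6 and 10 in delta A, B, C, E and F.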

How the results depend on the processing

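Settings with the length trend, the class, 1 class or libraries left out as out of place were chosen after seeing the data. Apart from single libraries left out, 86 gene counts stayed within 1.5-fold of the reported one and 104 moved; of values of named genes 1651 kept direction and side of the threshold, 156 fell short, 42 newly passed, 25 moved (sign changes of uncalled values among them) and 23 turned. Recovery of planted changes limits what a count of 0 can mean: 2-fold changes were found in 19.7% at best. Where a setting changed a result the cause was not tested. DESeq2 size factors moved no result past these bounds. Removing the length trend shifted the median of all genes by −0.215 in Fd5-5, −0.164 in PCP, −0.120 in delta D, 0.101 in delta C, 0.140 in delta F, 0.10 in HpoC against PCP and 0.151 in HpoC against Fd5-5. A fit within 1 class is not possible for Fd5-5, delta D, delta A, delta C and delta F against wild type or between the wild types.

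Gene counts with the length trend removed were 892 (Fd5-5), 681 (HpoC), 804 (HpoN+PH), 12 (HpoC against PCP), 0, 42 and 130 (HpoC, PCP and delta D against Fd5-5). Without the 8 out-of-place libraries they were 6723 (Fd5-5), 4158 (HpoC), 6804 (HpoN+PH), 5573 (PCP), 7248 (delta D), 6637 (delta B), 1630 (delta E), 6394 (HpoC against PCP), 3613 (HpoN+PH against PCP), 7294 (HpoC against HpoN+PH), 7565, 2926, 3569 and 2031 (HpoC, HpoN+PH, PCP and delta D against Fd5-5) and 6500 (between wild types); without the 11 they were the same but for 7150 (delta B), 2248 (delta E) and 6659 (wild types). With the class as a term they were 1322 (HpoC), 829 (delta D), 436 (delta A), 11 (delta B), 1346 (delta C), 968 (delta E), 29 (delta F), 90 (HpoC against PCP), 8 (HpoC against HpoN+PH), 0, 255, 242 and 461 (HpoC, HpoN+PH, PCP and delta D against Fd5-5) and 752 (wild types). Within 1 class they were 4658 (HpoC), 1487 (delta E) and, from arms of 1 out-of-place library each (HpoN+PH 1, PCP 5 and delta B 4), 3562, 221 and 0; between mutants they were 1166 (HpoC against PCP), 979 (HpoC against HpoN+PH), 0, 1185, 1225 and 568 (against Fd5-5, same order). In fits of only the 2 groups they were 5672 (Fd5-5), 18 (PCP), 6884 (delta D), 0 (delta B), 146 (delta E), 1 (HpoC against PCP), 0, 79, 35 and 471 (against Fd5-5). In 1 fit of all 42 libraries they were 1202 (Fd5-5), 1045 (HpoN+PH), 623 (PCP), 4458 (delta D), 1458 (delta B), 305 (delta E), 41 (HpoC against PCP), 1 (HpoN+PH against PCP), 2 (HpoC against HpoN+PH), 29, 420, 214 and 178 (against Fd5-5). The DESeq2 Wald test gave 1523 (Fd5-5), 827 (HpoC), 1306 (HpoN+PH), 1061 (PCP), 4355 (delta D), 1045 (delta E), 238 (HpoC against PCP), 68 (HpoN+PH against PCP), 142 (HpoC against HpoN+PH), 77, 560, 356 and 332 (against Fd5-5). The replicate block gave 720 (PCP), 2 (HpoC against PCP), 0, 0 and 27 (HpoC, PCP and delta D against Fd5-5), and no filter 1755 (delta D).

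Medians of the Yorkie targets stayed at 0.96 (Fd5-5), 0.44 (HpoC), 0.62 (HpoN+PH), 0.56 (PCP), 1.14 (delta D), −1.24 (delta A), −0.50 (delta B), −1.31 (delta C) and −0.99 (delta F) with an estimated correlation, and lost their calls. Their medians with the length trend removed, none called, were 0.073 (Fd5-5), 0.074 (HpoC), 0.092 (HpoN+PH), 0.077 (PCP), 0.28 (delta D), −0.51 (delta A), −0.12 (delta B), −0.40 (delta C) and −0.30 (delta F). With the class as a term they were −0.069 (Fd5-5), −0.062 (HpoC), −0.16 (HpoN+PH), −0.17 (PCP), 0.070 (delta D), −0.24 (delta A), 0.081 (delta B), 0.048 (delta E) and −0.14 (delta F), none called. Without the out-of-place libraries HpoC was at −0.23 and delta E at 0.066 (0.061 without the 11). Within 1 class they were −0.25 (HpoC) and 0.045 (delta E), and −0.28 (HpoN+PH), −0.035 (PCP) and −0.050 (delta B) from 1 library each. HpoC in a fit of 2 groups, at 0.46, was not called, and delta E without a filter, at −0.16, was. Of the 146 other list results called, 0 stayed so with an estimated correlation; with the class as a term 56 kept call and direction, 7 turned and 83 lost the call, and 82 results were called in all, 0 of them with an estimated correlation.

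The r with Fd5-5 was 0.31 for HpoC without the out-of-place libraries; 0.57 (PCP), 0.62 (delta D), −0.42 (delta A), −0.15 (delta B), −0.074 (delta C) and −0.072 (delta F) with the class as a term; 0.80, −0.60 and −0.58 for delta D, delta C and delta F with no filter and 0.80, −0.57 and −0.56 with the length trend removed; and −0.61 (delta C) and −0.60 (delta F) without the 11 libraries. Yorkie targets that differed from Fd5-5 across sequencers were 0 in each of the 5 mutants with the class as a term (edgeR), 13 (delta B) and 10 (delta E) without the 8 libraries, and 13, 16 and 10 (delta B, delta C and delta E) without the 11.

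Named genes that turned were these. In HpoC, ex was at −0.68 without the out-of-place libraries and −0.64 within 1 class, and ft at −0.59 and −0.56. Within 1 class, from 1 library each, HpoN+PH had ex at −0.62 and ft at −0.48, and PCP had pk at −0.0050. With the class as a term dally was at 0.083 (delta A) and 0.034 (delta F), ft at 0.22 (delta A), mt:ND3 at −0.53 (delta B; −2.85 within 1 class) and 28SrRNA:CR45837 at −0.99 (delta C). With the length trend removed ft was at 0.48 (delta A), 0.39 (delta B), 1.09 (delta C) and 0.66 (delta F). Without the out-of-place libraries ex was at −1.98 in HpoC against PCP and −2.52 in HpoC against HpoN+PH.

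Leaving out each library in turn, which leaves 1 of 2 in Fd5-5 and wild type of the X Plus, gave counts from 69 to 284 (Fd5-5), 105 to 398 (HpoC), 83 to 1402 (HpoN+PH), 57 to 2059 (PCP), 217 to 1100 (delta D), 109 to 5837 (delta B), 145 to 784 (delta E), 1 to 128 (HpoC against PCP), 0 to 76 (HpoC against HpoN+PH), 0 to 68, 0 to 14, 0 to 40 and 22 to 55 (HpoC, HpoN+PH, PCP and delta D against Fd5-5) and 43 to 1627 (wild types), the lowest against wild type of the X Plus always without its library 2. Yorkie medians ran from 0.26 to 0.55 in HpoC and −0.27 to 0.066 in delta E, r from 0.76 to 0.83 for delta D, −0.65 to −0.60 for delta C and −0.63 to −0.57 for delta F, and differing targets from 5 to 10 in delta B and 3 to 6 in delta E. Of named genes 900 such values kept direction and side, 226 fell short, 15 moved and 1 newly passed.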

Other observations

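In delta A wing hinge genes had 9 of 10 down and Hedgehog targets 8 of 9, the opposite direction to the X Plus mutants (camera adjusted p = 0.00334 and 0.00274, adjusted p = 0.641 with an estimated correlation for both). JAK/STAT genes had 7 of 9 down (camera adjusted p = 0.00440). Salivary gland genes had 8 of 8 up (camera adjusted p = 0.000391, for both adjusted p = 0.641 with an estimated correlation). Nuclear genes of the mitochondrial complexes had 22 up and 1 down of 28 (camera adjusted p = 0.000647, adjusted p = 0.695 with an estimated correlation). These counts were as many list-adjusted, but for the complexes, with 23 and 2. With the class as a term the salivary gland list kept its call at a median of 4.11 (adjusted p = 0.7945 with an estimated correlation), and the hinge (−0.19), Hedgehog (−0.55), JAK/STAT (−0.92) and complexes (−0.06) lists did not.

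In delta C the mitochondrial genome had 14 of 15 genes up (camera adjusted p = 0.00411, adjusted p = 0.697 with an estimated correlation) and the nuclear complexes 24 of 28 (camera adjusted p = 3.47e-06, adjusted p = 0.646 with an estimated correlation), as many list-adjusted. Cell cycle genes, not called there as reported, had 12 down and 1 up of 28 with the class as a term, at a median of −0.38 (camera adjusted p = 6.0e-05, adjusted p = 0.7945 with an estimated correlation). In delta D salivary gland genes had 6 of 9 down (camera adjusted p = 0.00134, adjusted p = 0.641 with an estimated correlation), Notch targets 5 of 14 down, 8 list-adjusted (camera adjusted p = 0.0168, adjusted p = 0.670 with an estimated correlation), and cuticle proteins 15 down and 1 up of 59, alike list-adjusted (camera adjusted p = 0.00400, adjusted p = 0.641 with an estimated correlation).

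Over the 36 lists and 10 comparisons with wild type, camera called 155 of 360 results, and 0 with an estimated correlation. The calls up and down, with the lowest and highest median, were: Yki targets 5 and 4 (−1.31 to 1.14), Hippo components 5 and 2 (−0.86 to 0.72), PCP genes 3 and 4 (−1.08 to 0.62), wing pouch 5 and 2 (−1.21 to 2.12), wing hinge 5 and 3 (−1.83 to 1.5), notum 5 and 1 (−1.10 to 1.54), peripodial 2 and 0 (−0.79 to 0.75) and myoblasts 1 and 0 (−0.63 to 0.88). Further, they were: trachea 0 and 0 (−0.52 to 0.29), hemocytes 0 and 1 (−2.04 to 1.08), fat body 2 and 0 (−2.58 to 7.53), salivary gland 1 and 3 (−8.96 to 5.01), muscle 2 and 5 (−4.78 to 4.42), neurons and sensory precursors 4 and 0 (−0.73 to 1.69), testis 0 and 0 (−1.63 to 0.83), cell cycle 0 and 3 (−0.37 to −0.11) and apoptosis 1 and 0 (−0.54 to 0.60). For the pathway lists they were: JNK and regeneration 0 and 0 (−0.57 to 0.90), JAK/STAT 5 and 4 (−1.81 to 1.92), Wg targets 3 and 0 (−0.36 to 0.80), Notch targets 5 and 2 (−1.44 to 1.88), Dpp targets 3 and 4 (−1.41 to 1.16), Hh targets 5 and 1 (−1.39 to 1.79), EGFR targets 0 and 0 (−0.74 to 0.64), junction and polarity 4 and 5 (−1.90 to 1.0), mitochondrial complexes 5 and 2 (−1.39 to 1.37) and glycolysis 1 and 4 (−1.12 to 1.09). Last, they were: ecdysone response 2 and 0 (0.15 to 1.54), immune effectors 0 and 0 (−1.46 to 1.53), heat shock 1 and 5 (−4.89 to 8.16), ribosomal proteins 5 and 5 (−2.65 to 2.66), cuticle proteins 1 and 5 (−1.25 to 1.57), detoxification 1 and 0 (−0.21 to 0.88), replication histones 0 and 3 (−1.52 to 0.63), mitochondrial genome 4 and 1 (−1.10 to 2.90) and dosage compensation and sex 0 and 0 (−1.44 to 1.35).

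The following genes were chosen after their values were seen. In 6 libraries (wild type 1 and 2 of the X Plus, PCP 5 and delta A 1, 2 and 3) Hsc70-4 was at 83.3 to 114 CPM, against 3635 to 15820 CPM in the other 36. There kto was at 3.26 to 5.78 CPM (14.1 to 296 in the others), the splicing gene Spx at 1.82 to 5.13 (107 to 175), Bap111 at 3.32 to 5.40 (19.7 to 320.1) and mei-38 at 0.765 to 1.66 (29.8 to 105). Ribosomal RNA took 13.9% to 17.4% of counts in those 6 libraries and 0.792% to 15.0% in the others.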
